A study of Arabidopsis thaliana with 8 samples.

How the data were processed

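RNA from leaves of 8 Arabidopsis thaliana strains was measured with 1 Agilent 4x44K array per strain. Per the labels' protocols, the parents carried the MseI gene and were heated for 3 h at 33 °C, and the progeny were grown for 4 weeks under 16 h of light and 8 h of dark. Per the labels' protocols, 200 ng of total RNA was labelled with Cy3, although the labels' molecule field names genomic DNA. Whether a sample was 1 plant or a pool is not given in the sources used here. The sample titles and the description texts give different strain numbers, and the titles were used. All 8 samples form 1 group with replicate numbers 1 to 8 in the order ExTQ002, ExTQ013, ExTQ015, ExTQ003, ExTQ005, ExTQ016, ExTQ018 and ExTQ019. No untreated strain was used here as a control. The arrays sat on 2 slides of 4, each slide scanned apart, so slide and scan cannot be separated.

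The intensity values of each array were made by the authors with Agilent Feature Extraction 11.0.1.1 and its 1-colour protocol, per the file headers, with background subtraction and spatial detrending and no scaling between arrays. The spot and background median intensity columns hold raw pixel values, per the file headers. The deposited series values are on a log2 scale with nearly equal quantiles in every column. The scale was read from the values, with a correlation of at least 0.997 between each column and the log2 median intensity of its own array, against at most 0.994 for any other array. The processing notes in the labels also name limma, and the step that made the series values is not given in the sources used here.

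The processed intensity was put on the log2 scale, spots with a non-uniformity or population outlier mark were set aside, and spots of the same probe were averaged. Of 37478 probes, 34 were left out because every spot had such a mark on an array. Each array was scaled by its 75th percentile. Of the 25665 loci, 541 had 2 or more probes, and the probe with the highest mean stood for the gene. Among 491 genes with several tested probes, 69 had probes whose values ran in opposite directions over the strains (r below 0). A gene was tested when its probe was well above background on at least 1 array, which left 22382 genes. Of the loci 25449 were found in the reference gene table, which gave symbols. The build of the array's gene models is not given in the sources used here, so no reference coordinates are printed and genes were placed by the order of their locus names.

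Each strain was compared with the 7 others with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg over genes within a strain). A gene was called at an adjusted p under 0.05 and a log2 difference of at least 1 in size. The spread comes from the 7 others, and the lone strain is assumed to vary as they do. Where a gene was not well above background in any of the others, or in the strain but in all of the others, the difference of a called gene is given as a bound, computed against the lowest level of a probe well above background on the same array. Where a gene was not well above background in the strain and was so in only some of the others, or was named for a chromosome segment, this is said beside its value. A p-value printed beside a bound is that of the scaled difference and not of the bound. For a gene not above background in the others, its spread is that of readings near background. The slides were compared with limma over all 35 splits of 4 against 4 arrays. On simulated differences in 22382 genes of ExTQ015, the test recovered 37.3% of 67 genes changed by 1.5, 56.7% of 67 changed by 3 and 74.2% of 66 changed by 5 on the log2 scale, with 8 false calls among 120. The simulation gave every array the spread of the 7 others, so it builds in the assumption about the lone strain.

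For chromosome segments, the difference of a strain from the median of the 7 others was taken for genes well above background on at least 6 of the 7 others and centred on its genome-wide median. Medians over windows of 20 genes were called when larger in size than the 95th percentile of the largest window median in 1000 random orders of the genes, and overlapping windows of the same sign were joined. A piecewise-constant division of each chromosome, with runs of at least 20 genes and differences limited to 1.5 in size, gave the longer stretches. Those with at least 100 genes and a median of at least 0.3 in size are reported with intervals from 2000 bootstrap draws over genes. Runs of 100 genes lowered by 0.4, 0.6 or 1.0 in shuffled values of ExTQ015 were found in 20 of 20 trials at each size over 19635 genes, with 2, 1 and 1 other segments called, and the division placed both ends within 10 genes in 18, 20 and 20 trials. The window threshold was set for each strain, at 0.40 in ExTQ015 and from 0.36 in ExTQ005 to 1.10 in ExTQ019. The trials thus do not measure how small a shift the windows find in strains with higher thresholds. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and numba 0.67.0.

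The 22 gene lists held 559 entries, all on the array: DNA damage response, double-strand break repair, heat shock, salicylic acid defence, jasmonate and wounding, abscisic acid with drought and cold, circadian clock, nuclear photosynthesis, anthocyanin and flavonoid, glucosinolate, senescence and dark-inducible, iron homeostasis, phosphate starvation, sulfur deficiency, cell cycle and replication, flowering time, floral organ markers, root markers, seed and embryo markers, oxidative stress, touch and rapid wounding, and DNA methylation and silencing. Each list was tested in each strain with limma's fry, which asks whether its genes move on balance one way, and Benjamini-Hochberg adjustment over all 176 pairs. Camera was run beside it, as was fry's test for change in either direction. In simulated values over 22382 genes of ExTQ015, fry recovered the heat shock list raised by 2 and called 0 other pairs. The simulated genes were drawn independently, while the heat shock genes had an estimated correlation of 0.37 in the test of ExTQ015. The simulation thus does not measure the error of fry on the real lists. Plastid genes (1 locus), mitochondrial genes (4 loci) and transposable elements were not analysed here as lists.

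The genes named were set by rule. They were, per strain, the 2 called genes with the largest differences in each direction that were well above background where they were high; the 12 most variable genes; the top 3 called members of a list that passed; the top 2 genes of each called segment; and the top 4 members of the DNA damage, break repair and heat shock lists. For the 26 segments of ExTQ019 this was narrowed to the largest difference per chromosome, and AT4G01380, AP1, BHLH38, BHLH39, CRU3 and CRA1 were added, all after their values were seen.

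The alternatives were quantile normalization, normexp background correction with an offset of 50, the deposited series values, scaling by the array median, other filters on dim probes, the mean of a gene's probes, slide as a block, the 3 others of the same slide, eBayes with trend and robust, adjustment over all strains, no size limit, windows of 10 and 50 genes, a single threshold for all strains and leaving out each other strain in turn. Normexp was run on the median spot intensity, since the files hold no mean intensity column, which departs from the plan. Added after the data were seen were the division into stretches and its limits, windows over probes of chromosome intervals, normexp by maximum likelihood, the series values and median scaling for the segments, counts outside the stretches of ExTQ019, fry's test for change in either direction, and counts without ExTQ016 and ExTQ019.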

Results

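Ex-TAQing is a way to rearrange a plant genome from within. A restriction enzyme gene, here the gene for MseI, is placed in the plant and the enzyme is switched on by mild heat, so that the chromosomes are cut at many sites at once and rejoined by the cell. Progeny of such plants can carry lost, gained or moved chromosome parts. The 8 arrays measured RNA in leaves of 8 diploid Arabidopsis thaliana strains descended from treated plants, with 1 array for each of ExTQ002, ExTQ013, ExTQ015, ExTQ003, ExTQ005, ExTQ016, ExTQ018 and ExTQ019. All 8 belong to 1 group, and strains are named by the sample titles, since the description texts give other strain numbers. No strain had a second array, so a strain is compared here only with the other 7, and the number of arrays limits the precision.

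Each array held 37478 probes, of which 26236 were named by a locus and stood for 25665 loci. The share of probes well above background ran from 61.3% in ExTQ015 to 67.7% in ExTQ016. The median spread of probes printed 10 times on the same array was 0.05 to 0.08 on the log2 scale (SD of spots). After removal of dim probes 22382 genes were tested. Levels are log2 intensities relative to the 75th percentile of their own array, so a level of 0 is a moderately bright gene.

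How alike the strains were is the first question the design allows. Lines of common descent can share most of their leaf transcriptome, and what differs between them can reflect both the genome and the state of each plant at harvest. Over all tested genes the correlation between 2 strains had a median of 0.949 over 28 pairs, from 0.878 for the least alike pair to 0.985 for the most alike pair. These correlations are across genes, and genes are not independent replicates. ExTQ019 was the least like the others, with a median correlation of 0.915 with them, and ExTQ015 the most, at 0.967. The first principal component held 54.3% of the variance and the second 19.3%. ExTQ019 lay far out on the second component, at −118.8, where the next lowest strain, ExTQ016, was at −28.1. Slide 1 held ExTQ002, ExTQ013, ExTQ015 and ExTQ003, and slide 2 held the other 4. Between the slides 0 genes were called by limma with Benjamini-Hochberg adjustment, with 2259 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.372.

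The genes that varied most across the 8 strains show what separated the plants as a whole. Leaves of genetically close lines can differ in genes that respond to nutrients, to attack by microbes and to developmental stage. Among 18920 genes well above background on all 8 arrays the median SD over strains was 0.30 (n = 8), and 1562 genes, or 8.26%, had an SD of at least 1. SPX3, a regulator made when phosphate runs short, had the largest SD, at 3.82, with its highest level in ExTQ013 at 2.61 and its lowest in ExTQ019 at −7.05. The phosphatase gene PEPC1 had an SD of 3.16 and the phosphate transporter gene PHT1;1 one of 3.08, both lowest in ExTQ019, as was AT5G20790, with an SD of 3.28. A second set was highest in ExTQ019. It held BGL2, which encodes a pathogenesis-related glucanase (SD 3.35), and LURP1 (SD 2.98), both in the salicylic acid defence list, TAT3 (SD 3.24), which is in the jasmonate and wounding list, and AT4G10500 (SD 3.48), AT1G13470 (SD 3.20) and AT5G10760 (SD 3.02), which are in no list. BGL2 ranged from −4.09 in ExTQ003 to 5.58 in ExTQ019. AT2G47050 (SD 3.16) and AT3G28750 (SD 3.09) were both highest in ExTQ018, at 0.64 and 0.52, and AT2G47050 was lowest in ExTQ019, at −7.44. Among genes well above background on at least 1 array, 3905 had an SD of at least 1.

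Genes apart in a single strain are a place to look for the mark of a rearranged genome. A broken or moved gene can fall silent, and a gene set beside a new promoter can switch on in a tissue where it is normally off. Each strain was compared with the 7 others, and a gene was called at an adjusted p under 0.05 with a log2 difference of at least 1 in size (limma, Benjamini-Hochberg within the strain). ExTQ019 had 985 genes higher and 1411 lower, and ExTQ016 had 309 higher and 1 lower. ExTQ002 had 7 higher and 12 lower, ExTQ015 had 11 higher and 1 lower, and ExTQ005 had 1 higher and 0 lower. No gene was called by limma in ExTQ013, ExTQ003 or ExTQ018, with 221, 388 and 375 genes at an unadjusted p under 0.05. Without ExTQ015 1 gene was called in ExTQ003, and without ExTQ016 18 were called in ExTQ018. Normexp called 5392 genes in ExTQ003, of which 5382 were higher, and adjustment over all strains called 7 genes in ExTQ013, 3 in ExTQ003 and 7 in ExTQ018. Quantile normalization called 2 in ExTQ013 and 3 in ExTQ018, and the deposited series values gave 2 in ExTQ003. The call rests on the assumption that the single array of a strain varies as the other 7 do, and a gene that also varies among the 7 is hard to call.

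In ExTQ015 the changes were few and large. AGG2, which encodes a gamma subunit of the heterotrimeric G protein, was higher by 10.37 ± 0.30 (SE of the difference, 1 array against 7) with a limma adjusted p of 4.16e-05. Its level was 3.67 in ExTQ015 against a mean of −6.70 ± 0.28 (SD, n = 7) in the others, of which 6 were above background. AT1G64260 was higher by 7.85 ± 0.26 with a limma adjusted p of 6.00e-05. It was well above background in the 7 others as well, at a mean level of −4.38 ± 0.23 (SD, n = 7). The 1 gene called lower was AT1G29350, which fell by 2.91 ± 0.21 with a limma adjusted p of 0.00637. The count for ExTQ015 fell from 12 genes to 7 without ExTQ002, to 6 without ExTQ013 or ExTQ018 and to 5 without ExTQ005, and normexp background correction left 0.

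In ExTQ016 most of the genes called higher were not above background in any other strain. For these genes the spread behind the p-value comes from readings near background. It does not measure how a gene that is on varies between plants. SESA3, a seed storage albumin gene, stood at 5.13 in ExTQ016 and was not above background in any of the 7 others, which makes it at least 6890.5-fold higher (limma adjusted p = 7.68e-05). AT5G38160, a gene without a symbol in the reference used, was at least 1509.7-fold higher with a limma adjusted p of 1.36e-05. Of the 309 genes called higher, 249 were not well above background in any other strain. The 1 gene called lower, AT4G01380 (limma adjusted p = 0.0305), was not above background in ExTQ016, so no size is given. AT4G01380 lay outside the naming rule and was chosen after its values were seen. Of the 310 calls, 9 genes were called when only probes well above background on all 8 arrays were kept, and 0 were called with normexp or against the 3 others of the same slide.

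ExTQ002 had 19 calls and the largest number of genes at an unadjusted p under 0.05 after ExTQ019, 2142. TFL1, whose product keeps the shoot tip from turning into a flower, fell by 4.22 ± 0.35 with a limma adjusted p of 0.0222. AT2G47880 fell by 4.68 ± 0.50 with a limma adjusted p of 0.0385. AT3G32270 was at least 10.97-fold higher and AT4G05350 at least 5.89-fold higher than in the others, none of which had them above background (limma adjusted p = 0.0193 for each). The count moved from 19 to 0 without ExTQ003, ExTQ005, ExTQ016 or ExTQ018, to 2 without ExTQ015, to 101 without ExTQ019 and to 347 without ExTQ013. With slide as a block 4 genes were called higher and 0 lower, so the calls of TFL1 and AT2G47880 were lost, and 0 genes were called by limma with normexp, in the deposited series values or within the slide, with 1068, 1941 and 1865 at an unadjusted p under 0.05. In ExTQ005 the gene called higher was AT4G24300, at least 7.77-fold above the background level of the others (limma adjusted p = 0.00657). This call was lost with normexp, in the deposited series values, with only probes above background on all 8 arrays, with trend and robust, within the slide and without ExTQ016 and ExTQ019.

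ExTQ019 differed from the others across a large part of the genome. AT2G44240 was higher by 9.84 ± 2.45 (limma adjusted p = 0.0341) and EDA36 by 8.97 ± 1.75 (limma adjusted p = 0.0144), both above background in 5 of the 7 others. The call of AT2G44240 in ExTQ019 was lost without ExTQ013 or ExTQ015, where the difference was 9.92 and 9.72. AACT1, which encodes an acyltransferase that makes defence compounds, fell by 7.11 ± 1.44 (limma adjusted p = 0.0166). AT5G55690 was not above background in ExTQ019 and was at least 67.8-fold lower than in the 7 others (limma adjusted p = 0.00968). Of the genes called, 41.1% were higher, and the share moved to 49.1% in the deposited series values and to 30% with normexp. Of 2396 genes, 2123 were called again with quantile normalization and 994 with normexp.

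Whether chromosome parts were lost or gained was asked through the RNA of neighbouring genes. A diploid plant that keeps 1 of 2 copies of a chromosome part tends to make less RNA from every gene in it, so that a run of neighbouring genes shifts together. Medians over 20 consecutive measured genes were compared with the largest medians in 1000 random orders of the same genes. Random orders also break up neighbours that are regulated together, so a called segment is not by itself a change in copy number. By this test the number of segments called was 26 in ExTQ019, 7 in ExTQ003, 2 each in ExTQ002, ExTQ013 and ExTQ016, and 1 each in ExTQ015, ExTQ005 and ExTQ018. The segments of ExTQ019 covered 866 genes, of which 809 lay in 24 segments that were lower and 57 in 2 that were higher. Those of ExTQ003 covered 404 genes, all lower as groups, and the segment of ExTQ015 covered 183 genes. With normexp no segment was called in ExTQ003. With a single threshold for all strains none was called in ExTQ015, ExTQ003, ExTQ005 or ExTQ018, and against the others of the same slide none was called in ExTQ005 or ExTQ018. The single segment of ExTQ018, of 25 genes, was not called without ExTQ002, ExTQ013 or ExTQ019 and grew to 58 genes without ExTQ003 and 56 without ExTQ005. In ExTQ002 the genes covered fell from 55 to 34 without ExTQ013, ExTQ015 or ExTQ003. In ExTQ013 they moved from 64 to 104 without ExTQ003 and to 37 without ExTQ005 or ExTQ018. In ExTQ005 they rose from 38 to 104 without ExTQ003 and to between 58 and 63 without ExTQ015, ExTQ016, ExTQ018 or ExTQ019. In ExTQ016 they moved from 67 to 43 without ExTQ002, 44 without ExTQ015 and 115 without ExTQ018.

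**Figure D1:**
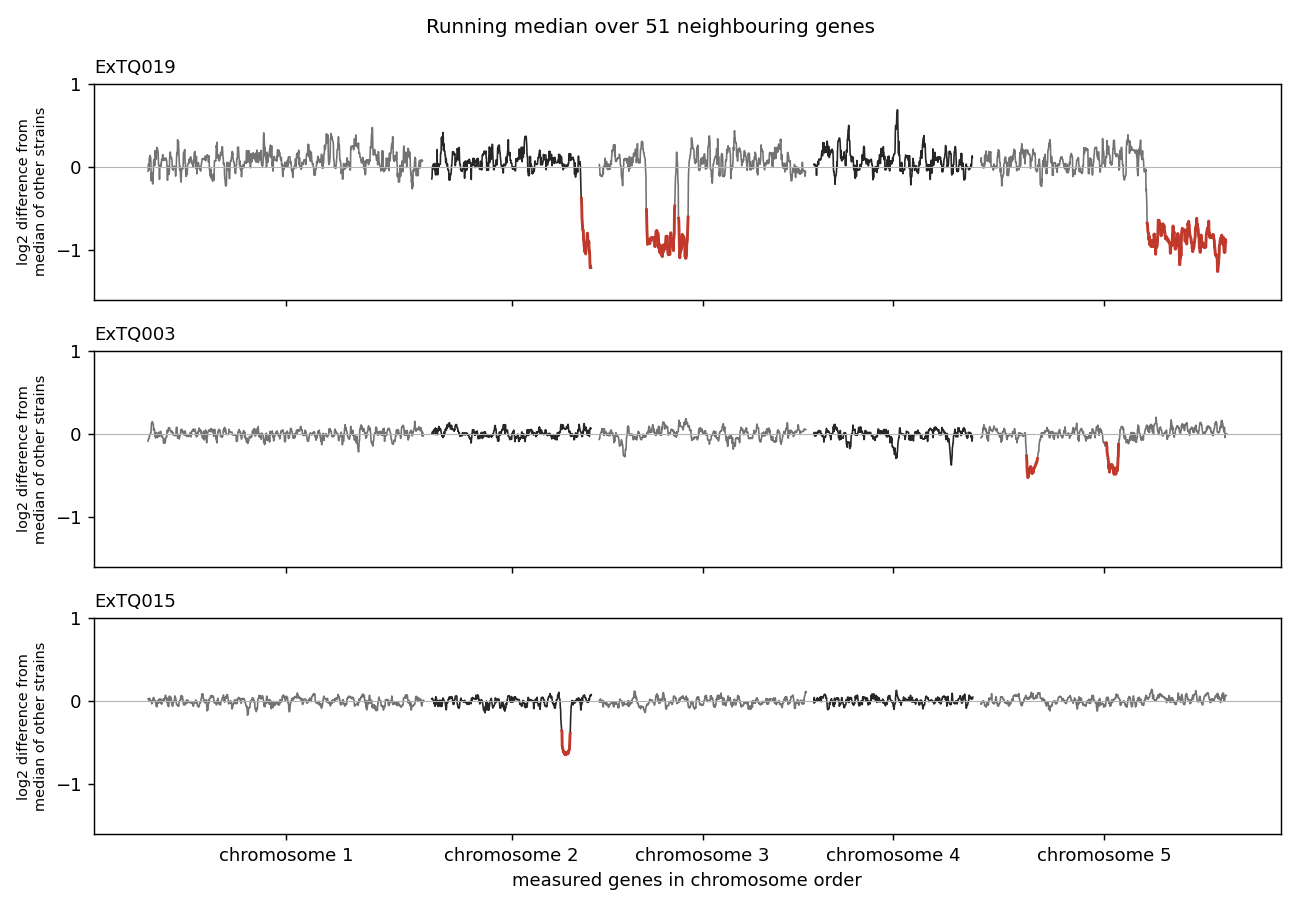
Running median over 51 neighbouring genes of the log2 difference between a strain and the median of the 7 others, along the 5 chromosomes, for ExTQ019, ExTQ003 and ExTQ015; the horizontal axis counts measured genes in order. Red lines mark the stretches of at least 100 genes, which sat near −1 in ExTQ019 and between −0.40 and −0.61 in ExTQ003 and ExTQ015.

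The sliding windows broke long shifted regions into pieces, so each chromosome was also divided into runs of constant level. This division, with its minimum of 100 genes and a shift of at least 0.3, was added after the segments had been seen. It gave 7 stretches in 3 strains, each named by its first and last measured gene in locus order. ExTQ019 had 4. On chromosome 2 the stretch from AT2G46160 to the last measured gene, AT2G48160, held 177 genes with a median shift of −1.01 (95% bootstrap interval −1.14 to −0.94). On chromosome 3 the stretch from AT3G11680 to PYD1 (AT3G17810) held 535 genes at −0.996 (−1.05 to −0.93). After a gap, the stretch from AT3G18560 to UCNL (AT3G20830) held 188 genes at −1.01 (−1.15 to −0.89). On chromosome 5 the stretch from AT5G49690 to the last measured gene, AT5G67640, held 1481 genes at −0.94 (−0.97 to −0.90). In the same genes the medians of the 7 other strains lay between −0.05 and 0.09. The bootstrap intervals resample genes within 1 array and do not cover differences between plants.

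ExTQ003 had a pair of stretches on chromosome 5 with smaller shifts. The one from AT5G11610 to AT5G14370 held 209 genes at −0.42 (−0.47 to −0.40), and 92.3% of its genes lay below 0. The one from AT5G39670 to AT5G42840 held 238 genes at −0.40 (−0.45 to −0.35), and 86.1% lay below 0, and with normexp its shift shrank to −0.062. In ExTQ015 the stretch on chromosome 2 from AT2G41610 to AT2G43530 held 163 genes at −0.61 (−0.65 to −0.58), with 94.5% of them below 0. The floral gene SHP2 had the largest difference in the called segment of ExTQ015, at −2.31 from the median of the others, and AT2G42990 followed at −2.21. SHP2 was higher in ExTQ015 than in the other strains of its slide, by 0.74. With 1 strain against 7, an exact permutation test of a single stretch cannot go below 0.125, so the shifts are given as sizes.

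**Figure D2:**
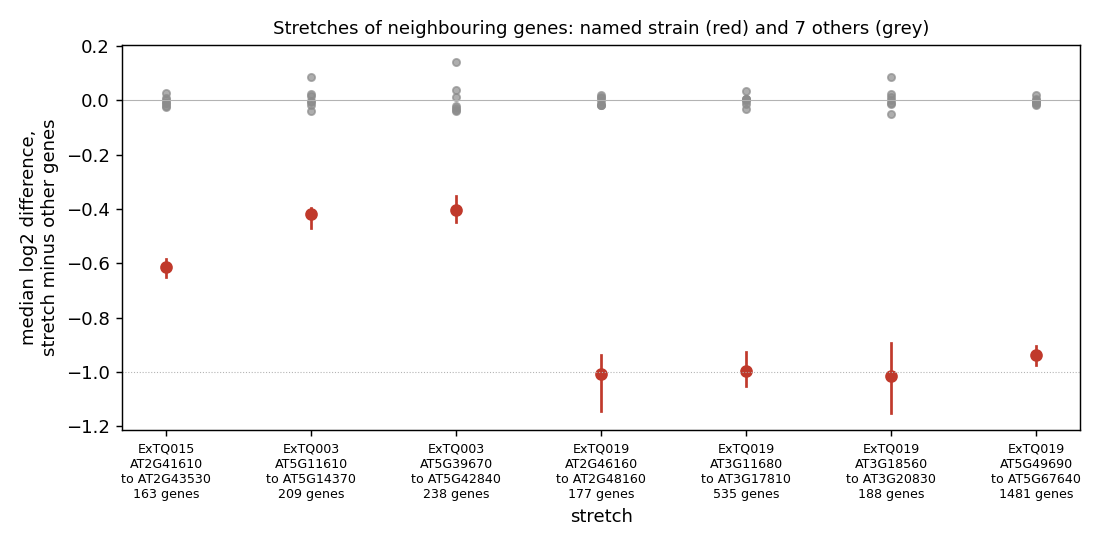
Median log2 difference from the other strains in each of the 7 stretches, with 1 point per strain; the named strain is red, with its 95% bootstrap interval over genes, and the others are grey. The 4 stretches of ExTQ019 lie between −0.94 and −1.01, while the other strains lie between −0.05 and 0.14 in all 7.

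The stretches of ExTQ019 held 2668 of the tested genes, or 11.9%. They held 773 of the 1411 genes called lower, or 54.8%, and 27 of the 985 called higher. Outside them lay 638 of the genes called lower and 958 of those called higher, with the adjustment over all genes. In the stretches of ExTQ015 and ExTQ003 0 genes were called by limma, with 185 and 506 genes tested there. Among the segments of ExTQ019 the largest differences from the median of the others were −7.50 for the acid phosphatase gene PAP14 on chromosome 2, 4.67 for AT3G13610 on chromosome 3, 6.68 for CRK7 on chromosome 4 and −7.12 for AT5G55690 on chromosome 5.

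A cluster of cysteine-rich receptor kinase genes on chromosome 4 was called in 7 of the 8 strains, all but ExTQ015. Its median difference was 0.87 in ExTQ002, 0.54 in ExTQ013 and 0.80 in ExTQ019. It was −0.39 in ExTQ003, −0.39 in ExTQ005, −0.55 in ExTQ016 and −0.34 in ExTQ018. CRK5 was apart by 3.64 in ExTQ002 and CRK13 by 2.81 in ExTQ013, while CRK6 was apart by −3.22 in ExTQ016 and CRK7 by −3.96 in ExTQ003. With normexp CRK6 and CRK7 were higher in ExTQ003, by 0.50 and 0.67. The genes of this cluster are alike in sequence, so signal shared between probes of neighbouring copies is uncertain. In each of the 7 strains the sign of the cluster was that of the salicylic acid defence list, which ran from 4.08 in ExTQ019 to −2.57 in ExTQ003. Each strain is set against the median of the others, so the 7 calls are not independent. In the division, runs of 20 genes there lay at 2.71 in ExTQ019, 1.86 in ExTQ002 and −1.55 in ExTQ016. A change by 1 of 2 copies gives at most 1 in size where RNA follows copy number. These sizes argue against such a change as the whole cause in those strains. The runs lay at 1.03 in ExTQ013, −0.68 in ExTQ003 and −0.69 in ExTQ005. Larger dosage changes, and any change in the other strains, cannot be told apart from shared regulation here. The cluster was the only segment called in ExTQ005 and in ExTQ018.

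Smaller segments were also called. In ExTQ002 a segment on chromosome 5 from CAM1 (AT5G37780) to NF-YC12 (AT5G38140) had a median of −0.90, led by AT5G37940 at −5.09 and AT5G37950 at −4.91. In ExTQ013 a segment on chromosome 1 from AT1G29350 to AT1G29710 had a median of −0.26, with AT1G29640 at 1.38 and AT1G29500 at −1.28. In ExTQ016 a segment on chromosome 1 from SYP124 (AT1G61290) to RPL3B (AT1G61580) had a median of −0.42, with SYP124 at 2.80 and AT1G61550 at −1.21. ExTQ003 had further segments at IAR3 (AT1G51760) to AT1G52100, with AT1G51920 at −4.08 and AT1G51890 at −2.86, and at AT4G35110 to HMGB5 (AT4G35570), with LHT7 at −2.79 and AT4G35380 at −1.29. Within its chromosome 5 stretches, cwINV6 was apart by −3.06, HSP17.6II by −2.82, Rap2.6L by −1.76, JAZ10 by −1.54, PUP12 by −3.27, CML37 by −2.53, AT5G40680 by −1.93 and AT5G40790 by 1.37. Of these genes in ExTQ003 normexp turned the sign of all but Rap2.6L, JAZ10 and AT5G40790. In the cluster on chromosome 4, CRK13 was apart by 3.45 in ExTQ002, CRK5 by −1.47 and CRK6 by −2.13 in ExTQ005, CRK23 by −2.72 in ExTQ016, and CRK24 by −1.25 and CRK22 by −1.14 in ExTQ018. CRK6 was apart by 2.76 in ExTQ013 and by −3.73 in ExTQ003. Several named genes were not well above background in the strain itself, so their differences depend on the background level: AT5G37950 in ExTQ002, CRK23 in ExTQ016, PAP14 and AT5G55690 in ExTQ019, and AT1G51920, CRK7, CRK6, HSP17.6II, AT5G40680 and PUP12 in ExTQ003.

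Gene lists drawn up before the data were examined asked whether whole programmes moved in a strain. Broken DNA sets off repair and checkpoint genes, stressed leaves raise defence, heat shock and nutrient genes, and flowers or seeds in a harvest bring their own transcripts. The 22 lists in 8 strains made 176 pairs. By limma's fry with Benjamini-Hochberg adjustment over all pairs, 2 passed an adjusted p of 0.05, and 18 had an unadjusted p under 0.05. Camera with a preset correlation of 0.01 called 71 pairs, and with an estimated correlation it called 0. Fry's test for change in either direction, adjusted in the same way and added after the data had been seen, called 10 pairs. Of these, 6 were in ExTQ019, where 2396 genes were called over all genes, and this test does not compare a list with other genes.

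Seed and embryo markers rose in ExTQ016 by a mean of 7.72 and a median of 8.68 over 20 genes, with 20 of 20 higher (limma fry adjusted p = 0.00107; adjusted p = 0.295 with normexp and 0.133 with camera and an estimated correlation). Of the 20 genes, 12 were called over all genes and 19 when adjusted over the list alone. SESA3 and SESA4 were at least 6890.5-fold and at least 721-fold higher (limma adjusted p = 7.68e-05 for each). CRU2, a cruciferin gene, was higher by 10.94 ± 0.93 (limma adjusted p = 9.88e-04) but was above background in only 2 of the 7 others, so its size rests in part on the background level. The SESA genes are close copies, so their separate values are uncertain. Only 6 to 8 of the 20 markers were well above background in 6 of the others, and 13 in ExTQ018, so the mean and the median of the list rest in part on the background level. Relative to its mean over the 8 strains the list stood at 6.76 in ExTQ016, 0.65 in ExTQ018 and between −1.65 and −0.89 in the remaining 6. In ExTQ018, against 7 others that include ExTQ016, it had a mean of 0.75 and a median of 0.05 with 11 of 20 higher and did not pass (limma fry adjusted p = 0.992). Floral organ markers were also higher in ExTQ016 and ExTQ018, by 1.91 and 2.26 with 19 of 19 higher in each, without passing (limma fry adjusted p = 0.955 for each). The same held in ExTQ003 and ExTQ005, by 1.52 and 0.97 with 19 of 19 higher in each, while the seed list lay at −1.11 and −1.18 there.

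**Figure D3:**
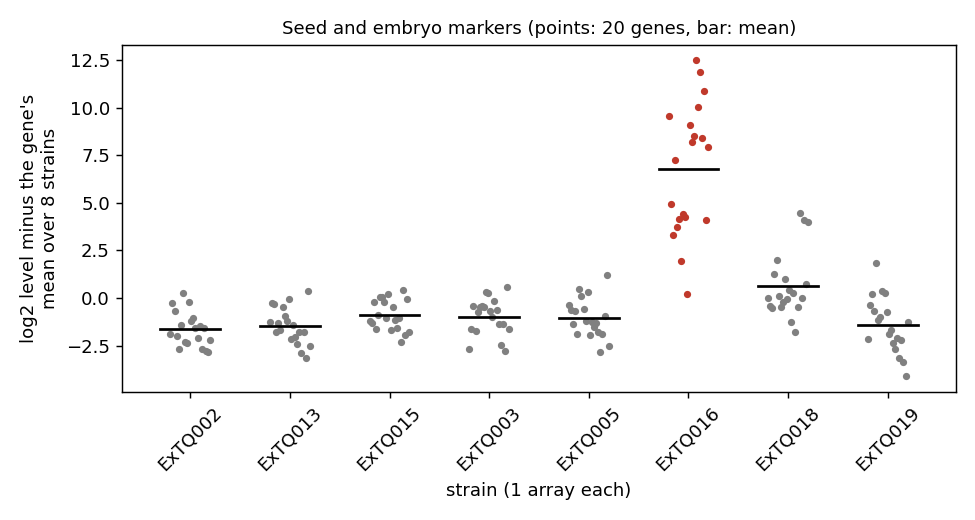
Log2 level of each of the 20 seed and embryo markers in each strain minus the gene's mean over the 8 strains, with 1 array per strain; points are genes and bars are means over genes. The bar of ExTQ016 stands at 6.76 and the next highest, that of ExTQ018, at 0.65.

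Cell cycle and replication genes fell in ExTQ002 by a mean of −0.93 over 32 genes, with 2 of 32 higher (limma fry adjusted p = 0.0313; adjusted p = 0.711 with camera and an estimated correlation). Over all genes 0 of them were called by limma, and 16 were called lower when adjusted over the list alone. The list's adjusted p was 0.0549 with quantile normalization, 0.134 with slide as a block and 0.295 with normexp. In the same strain floral organ markers lay at −4.82 with 0 of 19 higher and flowering time genes at −1.24, neither of which passed (limma fry adjusted p = 0.350 and 0.431). Whether the samples held the same tissues was not tested. The falls of these lists and of TFL1 in ExTQ002 thus cannot be put down to the strain alone.

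The DNA damage and repair lists did not pass the test for a shared direction, while in ExTQ019 both passed the test for change in either direction (limma fry adjusted p = 4.00e-06 for damage, with 8 of 21 genes higher, and 4.10e-07 for repair, with 12 of 28 higher). That test does not compare a list with other genes. In ExTQ019 1 of the 21 damage genes was called higher and 2 lower, and 0 of the 28 repair genes higher and 3 lower. Over all genes 2396 of 22382 were called, so neither list stood out by its share of calls. DNA damage response genes lay at 0.50 in ExTQ002 with 16 of 21 higher, at 0.37 in ExTQ013 with 18 of 21 higher, and between −0.23 and −0.07 in the others (smallest limma fry adjusted p = 0.686, in ExTQ002 and ExTQ013). Within the list, AT3G27630 fell by 1.35 ± 0.36 in ExTQ019 (limma adjusted p = 0.0415) and AGO2 rose by 1.17 ± 0.21 in ExTQ019 (limma adjusted p = 0.0115). The call of AT3G27630 in ExTQ019 was lost without ExTQ002, ExTQ013, ExTQ005, ExTQ016 or ExTQ018, with differences of −1.32, −1.28, −1.40, −1.33 and −1.29. NAC044 was 1.92 ± 0.74 higher in ExTQ002 and was not called. NAC085 was not called in ExTQ003 either. It was not above background there and was so in 4 of the 7 others, so its difference of −2.01 rests on the background level, and with normexp it was 2.89 higher. Double-strand break repair genes lay between −0.23 in ExTQ019 and 0.22 in ExTQ003 (smallest limma fry adjusted p = 0.955). RAD51B fell by 1.71 ± 0.26 in ExTQ019 (limma adjusted p = 0.00657), XRCC2 by 1.34 ± 0.17 (limma adjusted p = 0.00343) and MIM by 1.26 ± 0.27 (limma adjusted p = 0.0213). XRCC2 and MIM lie within the chromosome 5 stretch of ExTQ019. RECQ4A was lower in ExTQ002 by a difference of −1.08 ± 0.26 that was not called (limma adjusted p = 0.173).

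Defence and stress lists were widely spread without passing the test for a shared direction, and in ExTQ019 the heat shock and the anthocyanin and flavonoid lists passed the test for either direction (limma fry adjusted p = 9.25e-05 and 0.00795). Salicylic acid defence genes lay 4.08 above the others in ExTQ019, with 32 of 32 higher, 7 called over all genes and 13 adjusted over the list alone (limma fry adjusted p = 0.431). They lay at 2.08 in ExTQ002 and 1.41 in ExTQ013, again with 32 of 32 higher, and at −2.57 in ExTQ003 and −2.18 in ExTQ016 with 0 of 32 higher. Heat shock genes lay at 1.54 in ExTQ019 with 22 of 27 higher, 7 called higher and 2 lower, and 17 and 3 adjusted over the list alone (limma fry adjusted p = 0.431). HSP17.6A was higher there by 3.97 ± 1.16, HSP17.4 by 3.84 ± 1.35, HSP17.6II by 3.74 ± 1.25 and HSP23.6-MITO by 3.68 ± 1.12, with limma adjusted p from 0.0556 to 0.0948. Without ExTQ003 the first 3 of these were called, as HSP17.6A was without ExTQ002 and HSP23.6-MITO without ExTQ018. Anthocyanin and flavonoid genes lay at 1.62 in ExTQ019 with 6 called and 8 adjusted over the list alone, and oxidative stress genes at 1.31 with 3 called and 3 adjusted over the list alone (limma fry adjusted p = 0.434 for both). Touch and rapid wounding genes were higher in ExTQ019 for 16 of 21 members, with 3 called and 6 higher adjusted over the list alone, and lay at −1.15 in ExTQ016 with 0 of 21 higher (limma fry adjusted p = 0.955 and 0.431). Jasmonate and wounding genes ranged from −1.196 in ExTQ003 to 0.98 in ExTQ002 (smallest limma fry adjusted p = 0.447), with 0 called by limma in any strain.

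Lists tied to nutrition gave a further pattern across strains. Phosphate starvation genes lay at 2.93 in ExTQ002 and 2.91 in ExTQ013, with 21 of 22 higher in each, and at −2.42 in ExTQ019 with 3 of 22 higher (smallest limma fry adjusted p = 0.819). Iron homeostasis genes ranged from −1.01 in ExTQ002 to 0.91 in ExTQ018, and 2 were called higher and 2 lower in ExTQ019 (smallest limma fry adjusted p = 0.434). Relative to their means over the 8 strains, the iron regulator genes BHLH38 and BHLH39 stood at 4.61 and 4.60 in ExTQ005 and at −3.81 and −3.14 in ExTQ019. BHLH38 and BHLH39 were chosen after their values were seen. Sulfur deficiency genes ranged from −0.31 in ExTQ003 to 0.47 in ExTQ016 (smallest limma fry adjusted p = 0.434).

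Floral organ markers and flowering time genes were lowest in ExTQ002, and neither list passed the test for a shared direction. Floral organ markers lay at −4.82 in ExTQ002 with 0 of 19 higher, 0 called by limma over all genes and 17 lower adjusted over the list alone (limma fry adjusted p = 0.350). They lay at 2.26 in ExTQ018, 1.91 in ExTQ016 and 1.52 in ExTQ003, with 19 of 19 higher in each. AP1, a gene of floral meristems, stood at −7.01 in ExTQ002 and at 1.13 in ExTQ018, where a level of 0 is the array's 75th percentile. AP1 was chosen after its values were seen. Flowering time genes lay at −1.24 in ExTQ002, with 5 of 11 lower adjusted over the list alone (limma fry adjusted p = 0.431, and 0.0156 for either direction). Root markers ranged from −0.30 in ExTQ002 to 0.31 in ExTQ005 (smallest limma fry adjusted p = 0.312).

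No remaining list passed the test for a shared direction. Abscisic acid, drought and cold genes lay at −0.81 in ExTQ016 with 4 of 28 higher (smallest limma fry adjusted p = 0.686), and 3 were called lower in ExTQ019. Circadian clock genes lay at −0.48 in ExTQ019, with 2 called higher and 6 lower (limma fry adjusted p = 0.431, and 3.48e-05 for either direction). Nuclear photosynthesis genes lay at −0.38 in ExTQ013 with 0 of 49 higher (limma fry adjusted p = 0.446). Glucosinolate genes lay at −0.14 in ExTQ002, with 4 lower adjusted over the list alone (limma fry adjusted p = 0.369, and 0.0156 for either direction). Senescence and dark-inducible genes in ExTQ019 had a mean of −0.18 and a median of 0.07, on opposite sides of 0, with 3 called lower (limma fry adjusted p = 0.431, and 4.62e-07 for either direction), and stood at 0.78 in ExTQ013 with 22 of 23 higher. DNA methylation and silencing genes lay at −0.61 in ExTQ002 with 0 of 14 higher (limma fry adjusted p = 0.431).

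**Figure D4:**
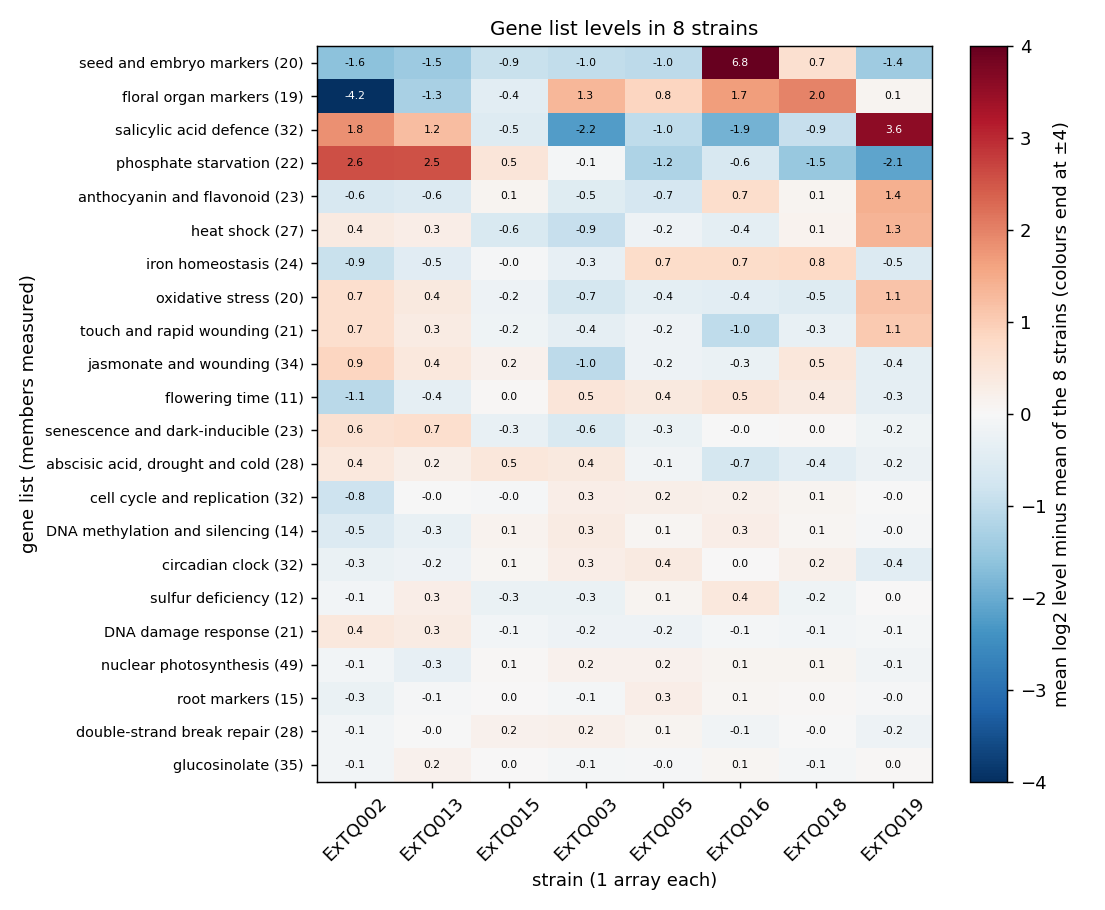
Mean log2 level of each of the 22 gene lists in each strain minus its mean over the 8 strains, as colours and numbers, with the members measured in brackets. Seed and embryo markers reach 6.76 in ExTQ016 and floral organ markers −4.22 in ExTQ002.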

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

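The tests chosen after the results had been seen were the loss of 1 copy in every plant or in part of the plants, an array-wide shift in ExTQ016, seeds in the leaf sample, the share of lower genes in the stretches and the quality of the ExTQ019 array. A value is listed here when the highest or lowest strain stood apart by a gap that was large against the range of all 8 (Dixon's test), or when a signal appeared in probes the comparisons did not use. Chance sets apart about 1 in 20 groups. Of 110 groups of 8 values, 35 had a strain apart, and 21 of these were among 68 named genes, most of which had been chosen for being apart. The 7 stretches were likewise chosen because 1 strain lay apart in them, so their place here adds nothing to that choice.

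ExTQ019 stood apart in its genes called higher (985) and lower (1411), in its place on the second principal component (−118.8) and in its genes in called segments (866). Genes with ExTQ019 apart were EDA36 (8.97), AACT1 (−7.11), AT5G55690 (−6.70), cwINV6 (6.56), AGO2 (1.17), RAD51B (−1.71), XRCC2 (−1.34) and MIM (−1.26), as log2 differences from the mean of the 7 others. The stretches of ExTQ019 lay apart by −1.01 on chromosome 2, by −0.996 and −1.02 on chromosome 3 and by −0.93 on chromosome 5. ExTQ003 lay apart in both of its chromosome 5 stretches, by −0.43 and −0.41, and ExTQ015 in its chromosome 2 stretch, by −0.61. The array of ExTQ003 had 1 saturated probe and the other 7 had 0.

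ExTQ016 stood apart in the seed and embryo list (7.72) and in SESA3 (14.25), AT5G38160 (12.51), SESA4 (11.44) and CRU2 (10.94). ExTQ002 stood apart in the cell cycle and replication list (−0.93) and in AT3G32270 (5.17), AT4G05350 (4.72), AT2G47880 (−4.68), TFL1 (−4.22) and RECQ4A (−1.08). In ExTQ015 the genes were AGG2 (10.37), AT1G64260 (7.85) and AT1G29350 (−2.91), and in ExTQ005 it was AT4G24300 (5.18). Where a gene was not above background in the others, or in the strain itself as for AT5G55690 in ExTQ019, the difference depends on the background level and the exact size is uncertain.

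The array also holds 8812 probes named by a chromosome interval in place of a gene. Of these, 2894 were well above background on at least 1 array and 1353 on all 8, and no comparison of genes used them.

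In the stretches of neighbouring genes that were lower together in ExTQ019, ExTQ003 and ExTQ015, a fault in 1 area of the array would lower spots of other genes as well, but probes next to the spots of the stretches had median differences of −0.00568 in ExTQ019, 5.28e-05 in ExTQ003 and 0.0216 in ExTQ015, where less than 0.1 in size had been set as the bound. These differences were centred on all probes outside the stretches, which include the neighbours. With 10781 neighbours in ExTQ019, a fall in them would thus be understated. The stretches kept at least 78.5%, 85.8% and 86.9% of their shifts in these strains under quantile normalization and in the deposited series values. A shift sets the genes of a stretch against other genes of the same array, so a factor common to the array cancels by construction. The shares kept therefore do not decide on scaling as the source. With normexp 1 stretch of ExTQ003 shrank to −0.062. In ExTQ019 the shift was −0.94 (95% bootstrap interval −0.97 to −0.90) over 1481 genes. That interval excludes −1 itself, while those of its other stretches include it (−1.14 to −0.94, −1.05 to −0.93 and −1.15 to −0.89). The intervals resample genes within 1 array and do not cover differences between plants. Loss of 1 of 2 copies would lie within 0.2 of −1 where RNA follows copy number. This range holds the shifts of ExTQ019 in the main scaling, but no DNA was measured. In the deposited series values the chromosome 2 stretch of ExTQ019 lay outside this range. Where RNA follows copy number, shifts of −0.42 in ExTQ003 and −0.61 in ExTQ015 are too small for loss of 1 copy in every plant. Whether RNA followed copy number was not tested. Loss in 50.5% and 69.4% of pooled plants would be needed. Such partial loss cannot be told apart from other dosages because any share is allowed and pooling is not stated. The design names no group that differs in copy number, so beyond these no biological explanation was tested.

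The second pattern is the genes higher in ExTQ016 that were near background elsewhere. A brighter array would move dim probes up, but 10822 probes not well above background on any other array had a median difference of −0.263, on the other side of 0 and just outside the bound of 0.2 set for no effect. Quantile normalization, which takes out an array-wide change, kept 92.5% of the median difference of the 249 genes (90.8% to 93.4%, bootstrap over genes). These genes were chosen for being high in ExTQ016 in the same values, and quantile normalization keeps the order of probes on an array. The share kept therefore does not decide on an array-wide change as the whole cause. With normexp the calls in ExTQ016 were lost. Developing seeds in the leaf sample are a candidate source. In ExTQ016 20 of the 20 seed and embryo markers were well above background, and between 6 and 8 were so in 6 of the others. SESA3, CRU3 and CRA1 stood at 5.13, 4.70 and 4.42 in ExTQ016, though levels of different probes do not measure relative amounts. In ExTQ018, however, 13 seed markers were above background where fewer than 10 had been set for every other strain. Floral organ markers lay at 1.91 in ExTQ016 and 2.26 in ExTQ018 with 19 of 19 higher in each. They were also higher for 19 of 19 in ExTQ003 (1.52) and ExTQ005 (0.97), where only 6 and 8 seed markers were above background. A rise of floral markers thus did not always come with seed markers. Seeds cannot be told apart from flowers or fruits in the sample or from seed genes switched on in leaves. No step that would remove seeds is given in the sources used here, and the design gives no group by which a biological explanation was tested.

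The third pattern is the 1411 genes lower in ExTQ019. The stretches held 54.8% of them, where at least 90% had been set for the stretches as the whole cause and less than 70% against it, so other genes were lower as well. A poor array was looked for in the median spread of spots and in the share of probes well above background, and 0 of these 2 measures of ExTQ019 lay outside the range of the other arrays. These are only 2 measures, and what lowered the genes outside the stretches stays open. No biological explanation was tested, since the design places ExTQ019 in the same group as the others.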

How the results depend on the processing

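The tests chosen after the results had been seen were the division into stretches, normexp by maximum likelihood, the series values and median scaling for the segments, the count outside the stretches of ExTQ019, fry for change in either direction and the count without ExTQ016 and ExTQ019. No paired analysis was possible because all 8 strains form 1 group and their numbers follow the order of deposition. All counts of genes apart in a strain are by limma with Benjamini-Hochberg adjustment, and a count is said to have moved when it changed by more than 1.5 times. Where no cause is given for a change, the cause was not tested.

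The median correlation of strain pairs moved only from 0.949 to 0.967 in the series values. The count of 0 genes in ExTQ013 held in all settings but quantile normalization and adjustment over all strains, with 221 genes at an unadjusted p under 0.05. The count of 2396 genes in ExTQ019 lay between 976 and 3995 over all settings. Without 1 other strain it lay between 1945 and 3179, and that of ExTQ016 between 270 and 366. No filter on dim probes and the mean of a gene's probes moved no count of calls. All 7 stretches kept a negative shift in every setting tried on them. The genes with an SD of at least 1 numbered 1562 and between 1157 and 1503 with normexp, slide centring or quantile normalization. They numbered 3905 when probes above background on at least 1 array were let in, which adds genes whose low levels lie near background.

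Of 1322 values for 63 pairs of a named gene and a strain, under 23 alternatives, 1164 kept their direction and their side of the threshold, 106 lost the call, 26 gained it and 26 changed sign. The sign changed in 13 pairs, and 21 pairs lost the call in at least 1 alternative.

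Quantile normalization called 2 genes in ExTQ013 where 0 were called before, 4 in ExTQ005 in place of 1 and 3 in ExTQ018 in place of 0. It left 1 list and strain pair of 2, as the cell cycle list in ExTQ002 went from an adjusted p of 0.0313 to 0.0549 (limma fry). Its adjusted p ranged from 2.38e-14 to 0.711 over all alternatives, and that of the seed list in ExTQ016 from 1.49e-41 to 0.295, with mean differences of −0.93 (2 of 32 genes higher) and 7.72 (20 of 20 higher) in the scaled values. Genes in called segments went from 64 to 37 in ExTQ013, from 67 to 122 in ExTQ016 and from 25 to 92 in ExTQ018. In ExTQ019 the chromosome 3 stretch of 535 genes went from −0.996 to −0.97 and the chromosome 5 stretch from −0.94 to −0.92. The cause was not tested.

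Normexp background correction was run on the raw median spot intensity in place of the processed intensity, so the intensity measure changed along with the background method. It called 5392 genes in ExTQ003, where 0 had been called, and 1010 in ExTQ019. It called 0 in ExTQ002, ExTQ015, ExTQ005 and ExTQ016, with 1068, 81, 43 and 256 genes at an unadjusted p under 0.05 (limma). After normexp the 5th percentile of levels was −1.87 on the ExTQ003 array and between −5.31 and −4.90 on the others, while before it lay between −10.21 and −9.38 on all 8. Dim genes were thus lifted on the ExTQ003 array far more than on the others, while the cause of the lower counts elsewhere was not tested. The median difference of all genes moved to 0.28 in ExTQ003, −0.16 in ExTQ019, −0.13 in ExTQ013 and −0.12 in ExTQ002. In ExTQ003 the sign turned for NAC085 (2.89), AT1G51920 (2.17), AT1G51890 (0.53), CRK7 (0.67), CRK6 (0.50), AT4G35380 (1.65), cwINV6 (0.90), HSP17.6II (2.46), AT5G40680 (2.54), PUP12 (2.52) and CML37 (0.53), all beyond the median, and for LHT7 (0.25), which lay below it.

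With normexp 1 list and strain pair was called, and neither the cell cycle list in ExTQ002 nor the seed list in ExTQ016 passed (limma fry adjusted p = 0.295 for each). Between the slides 1 gene was called in place of 0. Genes in called segments went to 31 in ExTQ013, 0 in ExTQ003 and 67 in ExTQ005, from 64, 404 and 38. The stretch of ExTQ015 went from −0.61 to −0.54. In ExTQ003 the chromosome 5 stretch from AT5G11610 went from −0.42 to −0.47 and the one from AT5G39670 from −0.40 to −0.062. In ExTQ019 the shift was −0.88 on chromosome 2, −0.88 and −0.91 on chromosome 3 and −0.83 on chromosome 5. Normexp by maximum likelihood called 5443 genes in ExTQ003 and 976 in ExTQ019, and 0 in ExTQ002, ExTQ015, ExTQ005 and ExTQ016, with 1056, 80, 42 and 249 at an unadjusted p under 0.05 (limma). It turned the same genes, by 2.195 for AT1G51920 in ExTQ003, by 2.48 for HSP17.6II in ExTQ003, and in that strain also NAC085 (2.91), AT1G51890 (0.55), CRK7 (0.69), CRK6 (0.53), LHT7 (0.27), AT4G35380 (1.67), cwINV6 (0.93), AT5G40680 (2.57), PUP12 (2.55) and CML37 (0.56). It gave 31, 0 and 67 genes in segments of ExTQ013, ExTQ003 and ExTQ005, and shifts of −0.54 in ExTQ015, −0.47 and −0.051 in ExTQ003, and −0.88, −0.88, −0.91 and −0.83 in ExTQ019.

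In the deposited series values 0 genes were called in ExTQ002 and ExTQ005 (limma, 1941 and 160 at an unadjusted p under 0.05), 5 in ExTQ015, 2 in ExTQ003 and 203 in ExTQ016. Genes in called segments were 34 in ExTQ013, 41 in ExTQ016, 0 in ExTQ018 and 1350 in ExTQ019. The stretch of ExTQ015 stood at −0.53, and those of ExTQ019 at −0.79 on chromosome 2, −0.85 and −0.85 on chromosome 3 and −0.81 on chromosome 5. Scaling by the array median called 1492 genes in ExTQ019, gave 37 genes in segments of ExTQ013 and a shift of −0.96 for the chromosome 5 stretch of ExTQ019. It moved the median difference of all genes to 0.25 in ExTQ002, 0.12 in ExTQ015, −0.23 in ExTQ016 and −0.25 in ExTQ018. The cause was not tested.

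Keeping only probes well above background on all 8 arrays called 10 genes in ExTQ002, 3 in ExTQ015, 0 in ExTQ005 (limma, 69 at an unadjusted p under 0.05) and 9 in ExTQ016. This filter tests 18920 genes in place of 22382 and leaves out by construction any gene that is on in a single strain. Signal over background thus limits what can be said of ExTQ016, where 249 of the 309 genes called higher were not well above background elsewhere, so their differences are bounds. With slide as a block 4 genes were called in ExTQ002 and 1 list and strain pair, the cell cycle list had an adjusted p of 0.134, and SHP2 in ExTQ015 stood at 0.74. The variance model with trend and robust called 1 gene in ExTQ002, 4 in ExTQ015, 0 in ExTQ005 (limma, 90 at an unadjusted p under 0.05) and 206 in ExTQ016. Adjustment over all strains called 118 genes in ExTQ002, 7 in ExTQ013, 19 in ExTQ015, 3 in ExTQ003, 5 in ExTQ005, 7 in ExTQ018 and 1018 in ExTQ019. With no size limit 3821 were called in ExTQ019. The cause was not tested for the block and the variance model.

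Against the 3 others of the same slide, with fewer arrays to give the spread, 0 genes were called in ExTQ002, ExTQ015, ExTQ005 and ExTQ016 (limma, 1865, 394, 304 and 707 at an unadjusted p under 0.05) and 3995 in ExTQ019. SHP2 stood at 0.74 in ExTQ015. Genes in called segments were 34 in ExTQ013, 162 in ExTQ003, 0 in ExTQ005 and 0 in ExTQ018 with this reference, and the chromosome 2 stretch of ExTQ019 stood at −1.06 and the 535-gene stretch at −0.96. With the model and the adjustment run anew on the 19709 genes outside the stretches of ExTQ019, 1366 genes were called in it, 808 higher and 558 lower, in place of 958 and 638 of the calls made over all genes. Without ExTQ016 and ExTQ019 0 genes were called in ExTQ005 (limma, 250 at an unadjusted p under 0.05) and 20 in ExTQ018.

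Fry for change in either direction called 10 list and strain pairs in place of 2, since it asks for no shared direction. Camera with a preset correlation called 71 list and strain pairs. With an estimated correlation it called 0, with adjusted p of 0.711 for the cell cycle list in ExTQ002 and 0.133 for the seed list in ExTQ016, where fry had 18 pairs at an unadjusted p under 0.05. Windows of 10 genes gave 42 genes in segments of ExTQ013, 18 in ExTQ015, 83 in ExTQ003, 60 in ExTQ005 and 96 in ExTQ019. Windows of 50 genes gave 84 in ExTQ002, 136 in ExTQ013, 817 in ExTQ003, 79 in ExTQ005, 278 in ExTQ016, 0 in ExTQ018 and 2591 in ExTQ019. A single threshold for all strains gave 33 in ExTQ002, 23 in ExTQ013, 27 in ExTQ016 and 0 in ExTQ015, ExTQ003, ExTQ005 and ExTQ018. That threshold takes the largest window median over the 8 strains in each random order, so by construction it is stricter for most strains. The filter that kept genes well above background on all 7 others moved no segment count.

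Leaving out each other strain in turn moved the count of ExTQ002 between 0 (without ExTQ003, ExTQ005, ExTQ016 or ExTQ018, with 1751, 1681, 1880 and 1713 genes at an unadjusted p under 0.05 by limma) and 347 (without ExTQ013). It was 2 without ExTQ015 and 101 without ExTQ019. That of ExTQ015 moved between 5 (without ExTQ005) and 13 (without ExTQ019), with 7 without ExTQ002 and 6 without ExTQ013 or ExTQ018. That of ExTQ003 moved from 0 to 1 without ExTQ015, and that of ExTQ018 from 0 to 18 without ExTQ016. Genes in called segments ranged from 34 to 78 in ExTQ002, from 37 to 104 in ExTQ013, from 37 to 104 in ExTQ005, from 43 to 115 in ExTQ016 and from 0 to 58 in ExTQ018. The lowest came without ExTQ013, ExTQ015 or ExTQ003 in ExTQ002, without ExTQ005 or ExTQ018 in ExTQ013, without ExTQ013 in ExTQ005, without ExTQ002 in ExTQ016 and without ExTQ002, ExTQ013 or ExTQ019 in ExTQ018. The highest came without ExTQ018 in ExTQ002 and ExTQ016 and without ExTQ003 in the others. The chromosome 2 stretch of ExTQ019 ranged from −1.05 (without ExTQ003) to −1.001, and its 535-gene stretch from −1.004 to −0.96 (without ExTQ016). The genes in segments of ExTQ015, ExTQ003 and ExTQ019 stayed between 183 and 209, 281 and 501, and 679 and 1007.

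Between the slides 0 genes were called by limma, with 2259 at an unadjusted p under 0.05. With a count of 0, all 35 splits of 4 against 4 arrays give at least as many by construction, so the splits say nothing about chance. The highest of the other splits called 679 genes, for ExTQ002, ExTQ013, ExTQ015 and ExTQ019 against the rest. It is the same division as by the sign of the first principal component, which held 54.3% of the variance. That component was computed from the same gene values, so the match is not independent of the count. This split differs from the slides only in the places of ExTQ003 and ExTQ019, so a part played by the slides in it was not tested.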

Other observations

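Windows of 20 probes named by chromosome intervals were compared with 1000 random orders in each strain, and all of these tests were chosen after the results for genes had been seen. The intervals are numbered on a build that is not given in the sources used here. In ExTQ019 a pair of segments lay on chromosome 5, from 19641853 to 22658059 with a median difference of −0.82 over 36 probes and from 23250301 to 24800975 with −0.82 over 31 probes. In ExTQ013 a pair lay on chromosome 2, from 2636973 to 3381436 with a median of 0.48 over 52 probes and from 3429057 to 6414599 with 0.34 over 33 probes. In ExTQ016 1 lay on chromosome 5, from 16004854 to 16993764 with a median of −0.41 over 21 probes. The genes inside these intervals were not measured as a group in ExTQ013 or ExTQ016, as genes were placed by locus order. No gene segment was called on chromosome 2 of ExTQ013 or chromosome 5 of ExTQ016. The thresholds of the 20-gene windows, 0.51 and 0.46, lay above the medians of the interval segments in size. Shifts of that size could thus be missed. Windows of 50 genes, with thresholds of 0.24 and 0.23, called none there either. The division by genes kept each of these chromosomes whole, at medians of 0.0047 and 0.0090. These medians do not describe a short part of a chromosome. No segment of interval probes was called in ExTQ002, ExTQ015, ExTQ003, ExTQ005 or ExTQ018.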
